A study of Homo sapiens with 24 samples.

How the data were processed

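PolyA-selected RNA of MOLM-13 and THP-1 cells was measured in 24 libraries, 3 for each of 4 treatments in each of 2 lines. Treatments were vehicle, LAA at 250 µM, olaparib at 1 µM and both, for 72 h. Per the labels' protocols, libraries came from column-purified RNA and a kit that does not mark the strand. Per the submitters' processing notes, the authors used HISAT2, SAMtools and DESeq2 with the genome build hg38, and versions were not given. The counting tool, its strand setting and the annotation release are not given in the sources used here. The deposited count table holds whole numbers per gene and library for 58735 genes, without normalization. The deposited FPKM table divides those counts by gene length and by 1 size per library, which is not the total of the column. The gene length in the deposited tables is that of the gene model. All 24 columns of each table were used. Gene symbols, identifiers, coordinates and biotypes are those in the deposited tables.

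Total counts per library were 18666259 to 25265870. Mitochondrially encoded genes took 6.63 to 11.02% of counts, the 10 most abundant genes 9.52 to 12.6%, and TMM scaling factors lay between 0.944 and 1.038.

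Each line was fitted on its own over its 12 libraries with edgeR 4.0.16 in R 4.3.3. Genes passed edgeR's filterByExpr at default settings, libraries were scaled by TMM, and group means were compared with the quasi-likelihood F test. P-values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. In each line the comparisons were each treatment against vehicle, the combination against LAA and against olaparib, and the interaction (combination minus LAA minus olaparib plus vehicle on the log2 scale). Differences between the lines in each treatment's effect were tested in a fit of all 24 libraries, as THP-1 minus MOLM-13. That made 15 comparisons. Levels are CPM with TMM scaling.

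Of 23 gene lists tested, 22 are described here and 1 was left out of the text. They were homologous recombination and Fanconi anemia repair, base excision repair and poly-ADP-ribosylation, DNA methylation and its oxidation, interferon-stimulated genes, DNA replication, mitosis, monocyte differentiation, the KMT2A fusion program, hypoxia-inducible factor targets, NRF2 and oxidative stress, iron handling, the unfolded protein and integrated stress response, cholesterol synthesis and uptake, NF-kB and inflammatory mediators, germline genes silenced by DNA methylation, apoptosis regulators, mitochondrially encoded genes, cytosolic ribosomal proteins, and markers of T and NK, B, erythroid and megakaryocyte, and epithelial and fibroblast cells. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, were run beside it. Of 123 list tests against vehicle 49 were called. Counts of called members are given over all genes tested and adjusted over the list alone. A further 8 lists were chosen after the data were seen: MHC class I and peptide loading, MHC class II, translation factors with 5' TOP messenger RNAs, cytosolic aminoacyl-tRNA synthetases, proteasome subunits, nucleic acid sensors, nuclear-encoded oxidative phosphorylation genes and replication-dependent histones.

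Named genes followed a rule. In each treatment against vehicle comparison they were the 6 largest increases and 6 largest decreases among protein-coding genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups' libraries, which chance gives in 10% of splits of 3 against 3. Up to 3 called members with the smallest adjusted p were added per list. In the other comparisons 3 per direction were named. TET1, TET2, TET3, TDG, DNMT1, DNMT3A, DNMT3B, PARP1, PARP2, CDKN1A, MYC, HMOX1, ITGAM and CD14 were looked at in every comparison, and their called values are given. The lists, this rule, the design and the other settings tried, 1 excepted, were set before the data were examined. Genes named outside the rule, such as those nearly silent in THP-1, were chosen after their values were seen. For a group with 0 counts a floor of 3 counts over the group was used, and intervals or floors cover counting error only.

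Overlaps between comparisons were counted by gene and direction and set beside the product of both call numbers over the genes tested. For comparisons sharing vehicle libraries, 20 sets of unchanged groups were simulated against them. GC content and length came from reference transcripts, and their trend was removed with a loess fit (span 0.3). Ribosomal protein genes were set beside 10000 random lists of like level, GC content and length. Group labels were reassigned in all 10 splits of 3 against 3, or in 100 drawn regroupings for interactions and line differences.

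Alternatives were size factors of the DESeq2 type, total-count scaling, DESeq2 1.42.0, no count filter, a filter of CPM 1 in 3 libraries, limma on log2 FPKM with pseudocounts 1 and 0.1, the compared groups alone, a replicate block, and leaving out each library in turn. One more, which left out genes differing between the lines, was added after the data were seen. Replicate numbers did not pair the libraries.

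The tests were first run on simulated counts with 200 changed genes, all with a mean log2 CPM of at least 1. The rates therefore do not cover genes of lower level or larger numbers of changed genes. For THP-1 with the combination, edgeR found 68.7% of 1.5-fold, 85.1% of 2-fold and 98.5% of 4-fold changes among 15735 genes, with 7 false calls of 191. For MOLM-13 with LAA it found 58.2, 80.6 and 100% among 15615 genes, with 10 false calls of 180. For THP-1 with LAA 25 of 208 calls were false, among 15740 genes. Variants, splicing and reads were not analysed here.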

Results

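Messenger RNA was sequenced from MOLM-13 and THP-1, 2 established human lines of acute myeloid leukemia cells that carry the KMT2A-MLLT3 (MLL-AF9) fusion. Cells received L-ascorbic acid (LAA, vitamin C, a cofactor of the TET enzymes that oxidize methylated cytosine) at 250 µM. Others received olaparib, an inhibitor of the poly-ADP-ribose polymerases PARP1 and PARP2, at 1 µM, both compounds together, or the vehicle of both. Treatment lasted 72 h. Each of the 8 groups had 3 libraries, 24 in all. Total counts per library ran from 18666259 to 25265870. Between 15186 and 15960 genes per library had at least 10 counts. Below, levels are mean CPM (counts scaled to a common library size) ± SD over 3 libraries, and log2 fold changes are given ± SE. Every gene comparison used 3 libraries per group. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples.

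The first question was which genes LAA alone changed. In THP-1 it raised interferon-stimulated genes, whose products act against viruses. IFI27 went from 26.2 ± 2.5 to 118 ± 12.5 CPM, a log2 fold change of 2.17 ± 0.14 (4.51-fold; edgeR adjusted p = 6.06e-11). IFI44L rose 3.14-fold (edgeR adjusted p = 6.06e-11), IFI44 2.76-fold and the membrane protein gene IFITM1 2.32-fold. Of 42 tested interferon-stimulated genes 36 rose, 0 fell and 6 were not called (40 and 0 adjusted over the list alone). Their median log2 fold change was 0.71 (camera adjusted p = 8.04e-59, and adjusted p = 0.00678 with an estimated correlation).

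Some genes of redox and sterol metabolism were also called higher with LAA in THP-1. AKR1C3, an aldo-keto reductase gene of the NRF2 oxidative stress list, rose 2.67-fold from 3.76 ± 0.52 to 10 ± 1.14 CPM (edgeR adjusted p = 0.00017), and AKR1C2 rose 1.27-fold. The AKR1C genes are near-identical copies whose reads the counting could split, so their values are uncertain. The NRF2 list had 6 of 31 genes higher and 0 lower (11 and 0 adjusted over the list alone). Its camera adjusted p was 1.01e-05, and the adjusted p was 0.0625 with an estimated correlation. The cholesterol list had 2 of 24 higher and 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 2.42e-07, adjusted p = 0.0625 with an estimated correlation). Its called genes were ACAT2 (1.29-fold), lost without LAA replicate 3 or vehicle replicate 2 (edgeR adjusted p = 0.189 and 0.254), and MSMO1 (1.25-fold), lost without each library but LAA replicate 2 (edgeR adjusted p from 0.0504 to 0.202). Among monocyte genes 5 of 40 rose and 2 fell (7 and 9 adjusted over the list alone), among them the lipid carrier APOE (1.76-fold higher), MNDA (1.35-fold higher), the calcium-binding alarmin S100A9 (1.35-fold higher) and the integrin ITGAM (1.34-fold lower, edgeR adjusted p = 0.006). CFP, the gene of complement properdin, fell 1.88-fold and the stress gene DDIT4 1.46-fold. IDH1, which makes the 2-oxoglutarate that TET enzymes use, rose 1.25-fold. Its call was lost without THP-1 vehicle replicate 2 (edgeR adjusted p = 0.0788).

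In all, 243 of 16331 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05 in THP-1 with LAA, 153 higher and 90 lower. At least 2-fold changes numbered 24 higher and 5 lower. The count fell to 152, 114 or 148 without vehicle replicate 1, 2 or 3, and to 129 without LAA replicate 3. Weak list shifts were called by camera for the KMT2A program (median -0.13, adjusted p = 0.00457, 0 higher and 1 lower of 28), mitosis (median 0.09, adjusted p = 0.00105, 0 and 0 of 40), the unfolded protein response (median 0.07, adjusted p = 0.00495, 1 and 0 of 35), ribosomal proteins (median -0.12, adjusted p = 2.42e-07, 0 and 1 of 48) and B cell markers (median 0.43, adjusted p = 0.0308, 0 and 0 of 6). With an estimated correlation these adjusted p were 0.287, 0.174, 0.213, 0.485 and 0.185. Counts higher and lower adjusted over the list alone were 0 and 3, 2 and 0, 3 and 0, 0 and 5, and 0 and 0. The KMT2A call was lost without vehicle replicate 1 or LAA replicate 2, and the B cell call without vehicle replicate 1, LAA replicate 1 or LAA replicate 3.

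In the libraries labelled MOLM-13, LAA raised S100A9 1.93-fold, from 208 ± 18.4 to 403 ± 38.6 CPM (log2 fold change 0.95 ± 0.09; edgeR adjusted p = 9.36e-06), and its partner S100A8 by the same fold. AKR1C3 rose 2.81-fold (edgeR adjusted p = 0.00226), the antigen-presentation gene HLA-DRA 2.22-fold (edgeR adjusted p = 0.000616) and the tetraspanin gene CD82 1.45-fold. FLT3, a growth factor receptor gene of the KMT2A program, was 4.6-fold lower, 35.9 ± 1.91 against 7.83 ± 1.65 CPM (edgeR adjusted p = 2.68e-08). The homeobox cofactor gene MEIS1 was 8.58-fold lower (edgeR adjusted p = 0.000301), and the inflammatory cytokine gene TNF fell 2.3-fold (edgeR adjusted p = 8.02e-06). EPB41L3 was 5.28-fold lower, ALDH1A3 5.31-fold, RAP2A 5.15-fold, RAB34 5.3-fold, EMD 5.89-fold and DLX5 8-fold. FLT3 lies on chromosome 13 from 28003274 to 28100592 (hg38, ENSG00000122025) and S100A9 on chromosome 1 from 153357854 to 153361027 (ENSG00000163220).

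By list, the KMT2A program had 0 of 28 genes higher and 4 lower with LAA in MOLM-13 (0 and 10 adjusted over the list alone; camera adjusted p = 2.71e-06, adjusted p = 0.248 with an estimated correlation). The cholesterol list had 6 of 24 higher and 0 lower (15 and 0 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 7.15e-10, adjusted p = 0.0914 with an estimated correlation). NRF2 genes had 4 of 31 higher and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.00153, adjusted p = 0.0914 with an estimated correlation). Interferon-stimulated genes had 5 of 41 higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.000769, adjusted p = 0.49 with an estimated correlation): IFITM1 rose 1.65-fold while TRIM22 fell 2.04-fold. Mitosis (median 0.08, camera adjusted p = 0.0106) and the mitochondrially encoded genes (median 0.22, camera adjusted p = 0.00237) shifted with 0 members called. Their adjusted p were 0.248 and 0.4 with an estimated correlation, and the mitosis call was lost without vehicle replicate 3 or LAA replicate 2. Monocyte genes went both ways, 3 higher and 5 lower of 39 (5 and 9 adjusted over the list alone), with NCF1 1.79-fold lower (NCF1 shares reads with near-identical copies).

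A total of 303 of 16160 genes passed the edgeR test with LAA in MOLM-13, 128 higher and 175 lower, with 12 and 62 at 2-fold or more. The count was 113 without vehicle replicate 2, 140 without vehicle replicate 3, 148 without LAA replicate 1, 469 without LAA replicate 2 and 188 without LAA replicate 3. Several of the lower genes were almost silent in THP-1. A set of 15 protein-coding genes on 10 chromosomes had at most 12 counts over the 12 THP-1 libraries and at least 20 over the 3 MOLM-13 olaparib libraries. They were RAB34, DLX5, EMD, PROK2, MTAP, ZFP57, NFE4, KLHL9, IGF2BP3, CNR2, SH3RF3, HOXC4, BPI, FUNDC1 and SLC26A5. All 14 genes tested in MOLM-13 were lower with LAA, 7 of them called. SLC26A5, at 0.0131 CPM with vehicle and 0.179 with LAA in MOLM-13, was not tested. Their summed level in MOLM-13 was 31.6 ± 0.888 CPM with vehicle, 5.34 ± 0.5 with LAA, 19.2 ± 1.37 with olaparib and 4.08 ± 1.04 with both. In THP-1 the group means were at most 0.361 CPM. Of the 175 genes lower with LAA in MOLM-13, 54 were among the 352 tested genes that stood higher in the MOLM-13 than in the THP-1 olaparib libraries. That was 15.3% of those 352 genes, against 0.723% of the other genes. Of 450 tested genes that stood lower in the MOLM-13 than in the THP-1 olaparib libraries, 26 were called higher with LAA and 10 lower. FLT3, MEIS1 and EPB41L3 belonged to those 352, so their lower level after LAA is given as a difference between libraries. FLT3 and MEIS1 are also on the KMT2A list, so its shift in MOLM-13, with LAA or both compounds, carries that limit. The set of 15 genes, its count limits and the 352 genes were chosen after the values were seen.

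**Figure D1:**
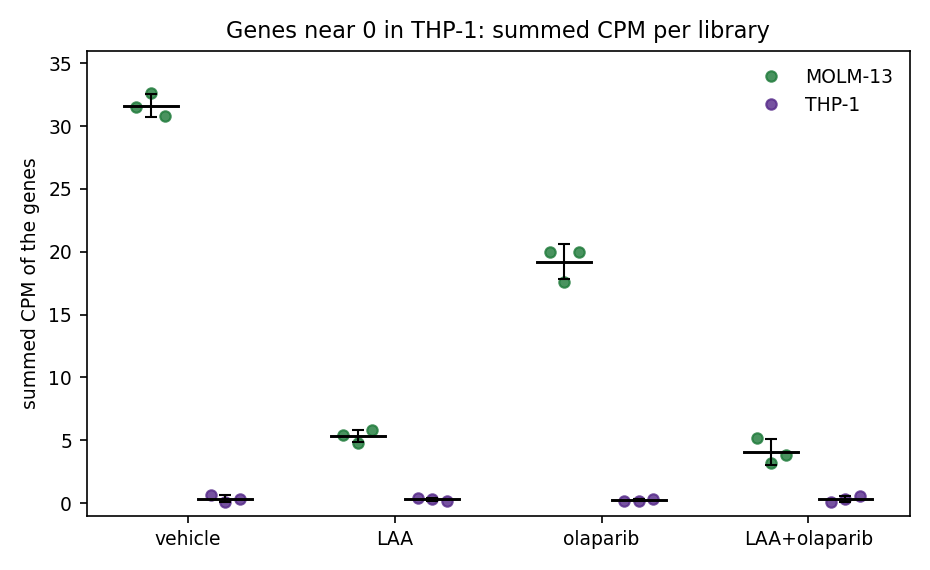
Summed CPM (y axis) of 15 genes with at most 12 counts over the THP-1 libraries, per library (points), by treatment (x axis) and line, with the mean (bar) and SD of 3 libraries. MOLM-13 vehicle libraries averaged 31.6 CPM, LAA libraries 5.34 and libraries with both compounds 4.08.

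The next question was what olaparib alone changed. In THP-1 it raised CYP1B1, a monooxygenase gene, 2.01-fold from 27.6 ± 1.86 to 55.5 ± 3.26 CPM (log2 fold change 1.01 ± 0.09; edgeR adjusted p = 6.78e-07). The pseudokinase gene TRIB3, a target of the integrated stress response, rose 1.68-fold from 66.5 ± 1.48 to 112 ± 13.2 CPM (edgeR adjusted p = 1.28e-06). The cell-cycle inhibitor CDKN1A rose 1.31-fold, from 117 ± 2.71 to 153 ± 5.51 CPM (edgeR adjusted p = 0.00248). The stress cytokine gene GDF15 rose 4.92-fold from 0.843 ± 0.0352 CPM (edgeR adjusted p = 9.13e-05) and ORM1, an acute-phase protein gene, 4.74-fold from 0.273 ± 0.182 CPM. DHCR7, the last enzyme of cholesterol synthesis, fell 1.4-fold (edgeR adjusted p = 0.0024).

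Interferon-stimulated genes had 9 of 42 members higher and 0 lower with olaparib in THP-1 (26 and 0 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 2.74e-20, adjusted p = 0.0282 with an estimated correlation). Cholesterol genes had 0 higher and 3 lower of 24 (0 and 14 adjusted over the list alone; median -0.21, camera adjusted p = 8.47e-14, adjusted p = 0.0186 with an estimated correlation). The unfolded protein and integrated stress response list had 2 of 35 higher (12 and 0 adjusted over the list alone; camera adjusted p = 1.64e-09) and monocyte genes 2 of 40 higher, among them the lysozyme gene LYZ at 1.32-fold, a call lost without vehicle replicate 1 (10 and 1 adjusted over the list alone; camera adjusted p = 9.48e-05). Mitosis genes shifted up by a median of 0.12 with 0 called (8 and 0 adjusted over the list alone; camera adjusted p = 3.2e-08) and hypoxia-inducible factor targets down with 0 higher and 1 lower of 41 (0 and 3 adjusted over the list alone; camera adjusted p = 2.43e-05). These 4 lists held with an estimated correlation, at adjusted p of 0.0186, 0.0186, 0.0186 and 0.0254. Camera calls for homologous recombination (median 0.06, adjusted p = 0.0296), mitochondrially encoded (median -0.11, adjusted p = 0.000958) and ribosomal protein genes (median -0.08, adjusted p = 4.41e-05) had adjusted p of 0.261, 0.392 and 0.612 with an estimated correlation. The recombination call was lost without vehicle replicate 2 or 3 or olaparib replicate 2, and the ribosomal call without olaparib replicate 2.

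In THP-1 with olaparib, 44 genes passed the edgeR test, 30 higher and 14 lower (36 and 9 with total-count scaling). The count was 19 without vehicle replicate 2, 15 without vehicle replicate 3, 16 without olaparib replicate 1 and 79 without olaparib replicate 3. In MOLM-13, 1 gene passed, again CYP1B1, which rose 1.85-fold from 19.7 ± 1.78 to 36.5 ± 1.66 CPM (log2 fold change 0.89 ± 0.12; edgeR adjusted p = 0.0138). CYP1B1 lies on chromosome 2 from 38066973 to 38109902 (ENSG00000138061). Its MOLM-13 call was lost without vehicle replicate 1, 2 or 3 or olaparib replicate 1, at edgeR adjusted p of 0.197, 0.158, 0.0514 and 0.0678. It was also lost with total-count scaling and on log2 FPKM with pseudocount 1 or 0.1, at adjusted p of up to 0.164. Without olaparib replicate 2, 7 genes passed. An unadjusted p under 0.05 was reached by 1354 of 16160 genes, against 808 by chance, and DESeq2 called 33.

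No list had a called member in MOLM-13 with olaparib (0 by edgeR in each). Adjusted over the list alone, 13 of 24 cholesterol genes and 5 of 41 hypoxia targets were lower, and 5 of 39 monocyte, 12 of 13 mitochondrially encoded and 2 of 41 interferon-stimulated genes higher. Camera called the cholesterol list lower (median -0.24, adjusted p = 4.58e-13) and the monocyte list higher (median 0.1, adjusted p = 0.00196), and both held with an estimated correlation at 0.0413. Interferon-stimulated genes (median 0.26, camera adjusted p = 7.08e-08), mitosis (median 0.1, 9.09e-05), hypoxia targets (median -0.12, 2.72e-05), mitochondrially encoded genes (median 0.54, 2.45e-13) and ribosomal proteins (median -0.12, 1.63e-05) were called with the preset correlation. With an estimated correlation their adjusted p were 0.323, 0.0834, 0.0978, 0.0689 and 0.655, and the ribosomal call was lost without vehicle replicate 1. Mitochondrial genes took 9.29 ± 1.51% of counts with olaparib and 6.71 ± 0.0329% with vehicle in MOLM-13. Olaparib replicate 3 stood apart at 11%, against 8.63% and 8.22% in replicates 1 and 2. This list was set beforehand as a sign of RNA quality.

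**Figure D2:**
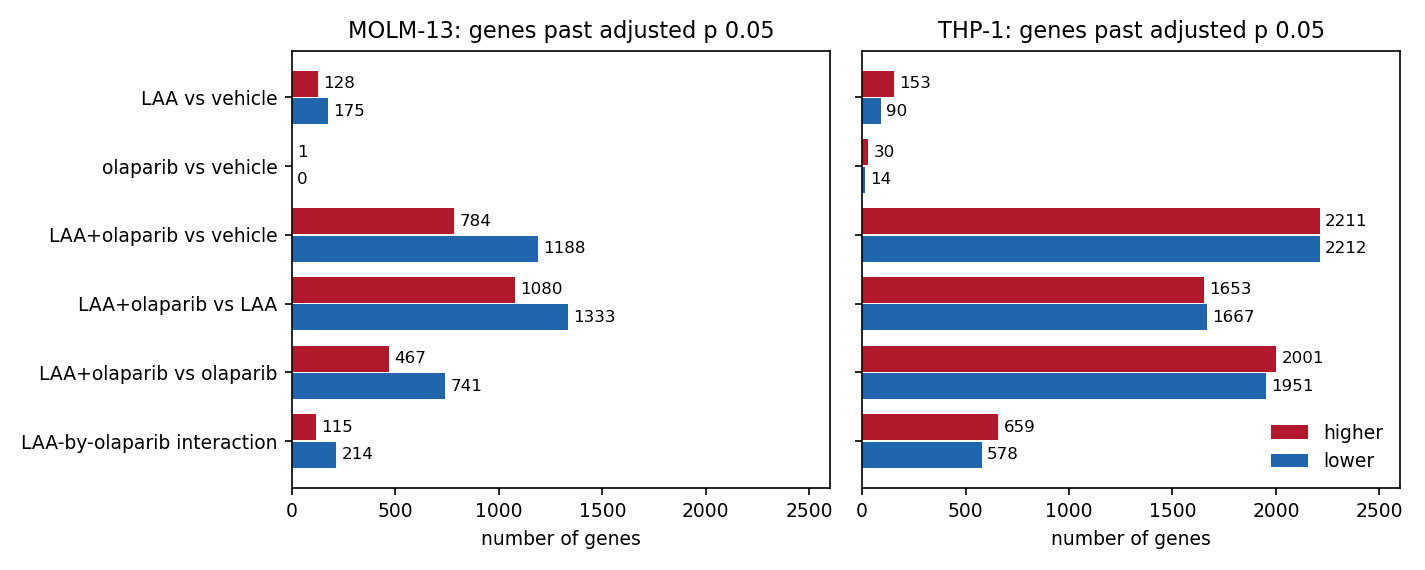
Number of genes (x axis) higher (red) or lower (blue) at an edgeR adjusted p of 0.05 in each comparison (y axis), per line. The combination called 1972 genes in MOLM-13 and 4423 in THP-1, against 303 and 243 for LAA and 1 and 44 for olaparib.

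The main question of the design was what the 2 compounds did together. In THP-1 the combination raised interferon-stimulated genes further than either compound. IFI44L rose from 8.46 ± 0.356 to 138 ± 4.48 CPM (log2 fold change 4.02 ± 0.1, 16.3-fold; edgeR adjusted p = 1.69e-20). IFI27 rose 17.6-fold to 462 ± 56.2 CPM, the antiviral synthetase gene OAS3 6.38-fold from 78.5 ± 7.51 to 501 ± 29.1 CPM (edgeR adjusted p = 5.42e-20), and IFITM1 6.23-fold. Of 42 genes on the list 40 rose and 1 fell, the same 40 and 1 counts as when adjusted over the list alone. The median was 2.12 (camera adjusted p = 9.35e-47, adjusted p = 0.00363 with an estimated correlation).

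Stress-response genes rose with them. TRIB3 rose 7.35-fold from 66.5 ± 1.48 to 489 ± 31 CPM (edgeR adjusted p = 2.18e-20), the chaperone gene HSPA5 1.93-fold to 1084 ± 38.3 CPM, the amino acid transporter gene SLC7A5 2.18-fold and SESN2 3.14-fold. The unfolded protein and integrated stress response list had 29 of 35 genes higher and 1 lower (31 and 1 adjusted over the list alone; median 0.59, camera adjusted p = 3.26e-22, adjusted p = 0.00227 with an estimated correlation). The largest increases were ORM1 (86.4-fold, from 0.273 ± 0.182 to 24 ± 3.41 CPM; edgeR adjusted p = 3.93e-16), the kelch-domain gene KLHDC7B (63.8-fold, to 40.2 ± 4.8 CPM; edgeR adjusted p = 6.97e-17), GDF15 (42.5-fold, to 36.2 ± 2.86 CPM; edgeR adjusted p = 1.8e-15) and LRRC2 (13.5-fold). KLHDC7B lies on chromosome 22 from 50545891 to 50551023 (ENSG00000130487) and ORM1 on chromosome 9 from 114323056 to 114326475 (ENSG00000229314).

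Sterol genes and hypoxia-inducible factor targets fell with the combination in THP-1. DHCR7 fell 3.4-fold from 69 ± 2 to 20.3 ± 0.671 CPM (edgeR adjusted p = 1.4e-15), INSIG1 2.87-fold and LSS 2.61-fold. The cholesterol list had 0 higher and 22 lower of 24 (0 and 23 adjusted over the list alone; median -0.91, camera adjusted p = 1.1e-20, adjusted p = 0.00247 with an estimated correlation). Among hypoxia-inducible factor targets the aldolase gene ALDOC fell 6.85-fold, the mitophagy gene BNIP3 2.76-fold and NDRG1 2.47-fold, with 1 higher and 32 lower of 41 (1 and 34 adjusted over the list alone; median -0.53, camera adjusted p = 3.16e-14, adjusted p = 0.00227 with an estimated correlation). The largest decreases were the heparan sulfatase gene SULF2 (15.5-fold, 30.9 ± 2.03 to 1.97 ± 0.299 CPM; edgeR adjusted p = 5.19e-17), TBC1D30 (12-fold), the adhesion gene JAML (11.5-fold), LSP1 (9.41-fold) and TMEM45A (7.15-fold). SULF2 lies on chromosome 20 from 47656348 to 47786616 (ENSG00000196562). FCGR2B was 9.99-fold lower, a value made uncertain by its near-identical copies.

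Proliferation and repair genes moved by smaller folds. DNA replication genes had 15 higher and 2 lower of 41 (18 and 2 adjusted over the list alone; median 0.14, camera adjusted p = 0.000643, adjusted p = 0.014 with an estimated correlation), among them the helicase subunit gene MCM7 (1.55-fold), CDC6 (1.45-fold) and ORC6 (1.59-fold). Homologous recombination genes had 10 higher and 3 lower of 38 (11 and 3 adjusted over the list alone), with BRCA2 at 1.49-fold and XRCC2 at 1.54-fold, and mitosis genes 11 higher and 7 lower of 40 (12 and 10). Neither list was called by camera, nor was base excision repair (7 and 2 of 29, 7 and 3 adjusted over the list alone, with the glycosylase genes NEIL3 1.4-fold higher and UNG 1.24-fold lower). Ribosomal protein genes had 0 higher and 40 lower of 48 (1 and 42 adjusted over the list alone; median -0.32, camera adjusted p = 9.29e-12, adjusted p = 0.537 with an estimated correlation), with RPLP0 1.35-fold and RPL7 1.36-fold lower. The KMT2A program had 1 higher and 14 lower of 28 (1 and 14 adjusted over the list alone; camera adjusted p = 0.000593, adjusted p = 0.313 with an estimated correlation), with MYC 1.44-fold and BCL2 1.54-fold lower.

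Genes of DNA methylation and its oxidation had 10 higher and 4 lower of 26 (11 and 5 adjusted over the list alone). Their median was -0.01, their mean 0.09 and the list was not called, and the sign of the median depended on the scaling. DNMT1, the maintenance methyltransferase, rose 1.17-fold (edgeR adjusted p = 0.00558) and GADD45A 1.8-fold, while DNMT3A fell 1.29-fold (edgeR adjusted p = 0.00269). TET1 was 1.64-fold lower (edgeR adjusted p = 0.00679), a call lost without vehicle replicate 1 (edgeR adjusted p = 0.0846). TDG, which excises oxidized methylcytosine, was 1.17-fold higher, a call lost without vehicle replicate 2 or 3 or combination replicate 2 (edgeR adjusted p = 0.122, 0.0534 and 0.078). TET2, TET3, DNMT3B, PARP1 and PARP2 were not called, with log2 fold changes of -0.18, 0.07, -0.21, 0 and -0.04.

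Differentiation and inflammation genes went both ways in THP-1. Among monocyte genes 8 rose and 14 fell of 40 (8 and 15 adjusted over the list alone): LYZ rose 2.68-fold and CD14, a lipopolysaccharide receptor, 2.74-fold, while S100A9 fell 2.62-fold, FCER1G 2.11-fold and ITGAM 1.98-fold (edgeR adjusted p = 1.53e-09). NF-kB and inflammatory genes had 5 higher and 5 lower of 22, with CCL5 1.64-fold higher and TNF 1.93-fold lower. NRF2 genes had 9 higher and 4 lower of 31, with the cystine transporter SLC7A11 1.68-fold and HMOX1 1.51-fold higher. Iron genes had 6 and 6 of 23, the zinc and iron transporter SLC39A14 rising 1.62-fold and the transferrin receptor TFRC falling 1.54-fold. Apoptosis regulators had 7 higher, among them PMAIP1 at 1.84-fold, and 5 lower of 32. Mitochondrially encoded genes had 4 higher and 1 lower of 13, B cell markers 1 higher and 0 lower of 6 (PAX5, 2.13-fold), and epithelial and fibroblast markers 1 and 1 of 6. CDH1 had 0 counts in the combination libraries against 39 in the vehicle libraries, at least 12.7-fold lower with a floor of 3 counts over the group. The epithelial list's median was -0.12 with CDH1 at that bound. Camera called none of these 8 lists. Counts adjusted over the list alone were 6 and 5 (NF-kB), 11 and 5 (NRF2), 7 and 6 (iron), 8 and 6 (apoptosis), 6 and 1 (mitochondrial), 1 and 0 (B cell) and 1 and 1 (epithelial). T and NK cell (1 higher and 0 lower of 4), germline (0 and 1 of 3) and erythroid markers (0 and 0 of 3) had too few tested members.

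Altogether 4423 genes passed the edgeR test in THP-1 with the combination, 2211 higher and 2212 lower, 401 and 282 of them by 2-fold or more. CDKN1A rose 1.45-fold (117 ± 2.71 to 170 ± 6 CPM; edgeR adjusted p = 1.7e-07).

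In MOLM-13 the combination also raised interferon-stimulated genes. IFIT2, which binds viral RNA, rose 6.29-fold from 4.78 ± 0.592 to 30.1 ± 3.9 CPM (log2 fold change 2.65 ± 0.15; edgeR adjusted p = 7.1e-10). IFI27 rose 10.3-fold to 35.7 ± 9.66 CPM, IFI44L 8.35-fold, IFI44 8.24-fold and IFIT3 4.93-fold. The list had 36 higher and 1 lower of 41 (38 and 1 adjusted over the list alone; median 1.34, camera adjusted p = 1.69e-36, adjusted p = 0.011 with an estimated correlation). KLHDC7B rose 18.3-fold from 0.392 ± 0.391 to 7.14 ± 0.947 CPM (edgeR adjusted p = 1.77e-05) and GDF15 7.83-fold to 10 ± 0.971 CPM. TRIB3 rose 4.11-fold from 54.7 ± 0.71 to 225 ± 11.8 CPM (edgeR adjusted p = 3.56e-12), ATF5 1.92-fold and SLC7A5 1.75-fold, and the stress response list had 17 higher and 1 lower of 35 (22 and 1 adjusted over the list alone; median 0.27, camera adjusted p = 1.77e-14, adjusted p = 0.0027 with an estimated correlation).

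Sterol genes fell in MOLM-13 as well. DHCR7 fell 2.99-fold from 71.9 ± 6.33 to 24.1 ± 2.46 CPM (edgeR adjusted p = 1.67e-09) and MSMO1 2.87-fold, and the cholesterol list had 0 higher and 22 lower of 24 (0 and 24 adjusted over the list alone; median -0.8, camera adjusted p = 1.39e-27, adjusted p = 0.00306 with an estimated correlation). Of 41 hypoxia targets 0 rose and 24 fell (0 and 31 adjusted over the list alone; median -0.49, camera adjusted p = 5.43e-18, adjusted p = 0.0041 with an estimated correlation), with ALDOC 5.56-fold, the glucose transporter SLC2A3 4.43-fold and NDRG1 2.26-fold lower. LSP1, an actin-binding leukocyte gene, fell 18.3-fold from 20.2 ± 1.78 to 1.07 ± 0.415 CPM (edgeR adjusted p = 1.52e-10), SULF2 from 23.7 ± 1.75 to 2.21 ± 0.823 CPM, and ICAM5 10.4-fold. S100A9, which LAA alone had raised, fell 3.07-fold to 68 ± 6.27 CPM (edgeR adjusted p = 1.67e-09). S100A8 fell 2.68-fold and TNF 6.12-fold. Monocyte genes had 5 higher and 10 lower of 39 (6 and 14 adjusted over the list alone; camera adjusted p = 0.00268, adjusted p = 0.0169 with an estimated correlation), and NF-kB genes 0 higher and 3 lower of 23 (0 and 3 adjusted over the list alone; camera adjusted p = 0.0386, adjusted p = 0.106 with an estimated correlation), a list call lost without vehicle replicate 3 or combination replicate 3. FLT3 (3.59-fold), MEIS1 (11.2-fold), DLX5 (11.7-fold) and EMD (11.7-fold) were lower again, and 118 of the 352 genes higher in MOLM-13 than in THP-1 olaparib libraries were among the 1188 lower genes (33.5%, against 6.67% of other genes). Of 450 tested genes lower in MOLM-13 than in THP-1 olaparib libraries, 123 were called higher with the combination and 46 lower. IGF2BP3 had 0 counts with the combination and 88 with vehicle, at least 27.6-fold lower with the same floor.

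DNA replication genes had 8 higher and 0 lower of 41 in MOLM-13 (10 and 0 adjusted over the list alone; camera adjusted p = 0.000681, adjusted p = 0.011 with an estimated correlation), with MCM10 at 1.39-fold and MCM7 at 1.32-fold. Homologous recombination had 5 higher and 1 lower of 38 (7 and 2 adjusted over the list alone; camera adjusted p = 0.00276, adjusted p = 0.189 with an estimated correlation), with BLM at 1.36-fold and EXO1 at 1.33-fold, and mitosis 6 higher and 0 lower of 40 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00276, adjusted p = 0.127 with an estimated correlation), with CDC20 at 1.29-fold. Ribosomal proteins had 0 higher and 43 lower of 48 (0 and 48 adjusted over the list alone; median -0.47, camera adjusted p = 1.55e-19, adjusted p = 0.189 with an estimated correlation), with RPL3 and RPLP0 each 1.44-fold lower. Mitochondrially encoded genes had 7 higher and 0 lower of 13 (10 and 0 adjusted over the list alone; camera adjusted p = 5.06e-05, adjusted p = 0.189 with an estimated correlation). The KMT2A program had 2 higher and 5 lower of 28 (2 and 6 adjusted over the list alone; camera adjusted p = 0.0271, adjusted p = 0.401 with an estimated correlation), a call lost without combination replicate 1. Camera called none of base excision repair (1 and 0 of 29), DNA methylation (1 and 2 of 26), NRF2 (3 and 5 of 31), iron (2 and 1 of 22), apoptosis (1 and 5 of 32), T and NK (0 and 1 of 5), B cell (0 and 0 of 5) or epithelial genes (0 and 0 of 5). Adjusted over the list alone, NRF2 genes had 6 and 6, and the other lists of that sentence had the counts given. The base excision list had a median of -0.04 and a mean of 0.02. CDKN1A fell 1.39-fold, from 144 ± 3.94 to 104 ± 5.79 CPM (edgeR adjusted p = 8.09e-05), and ITGAM 1.69-fold. MYC was 1.22-fold lower, a call lost without combination replicate 3 (edgeR adjusted p = 0.0608). No TET, DNMT, TDG or PARP gene was called, the smallest edgeR adjusted p being 0.0886 for PARP1.

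In this comparison 1972 genes passed the edgeR test, 784 higher and 1188 lower, 130 and 219 of them by 2-fold or more. With total-count scaling the split was 1096 higher and 934 lower. Leaving out vehicle replicate 1, combination replicate 2 or combination replicate 3 gave 1179, 1043 or 1176 genes.

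**Figure D3:**
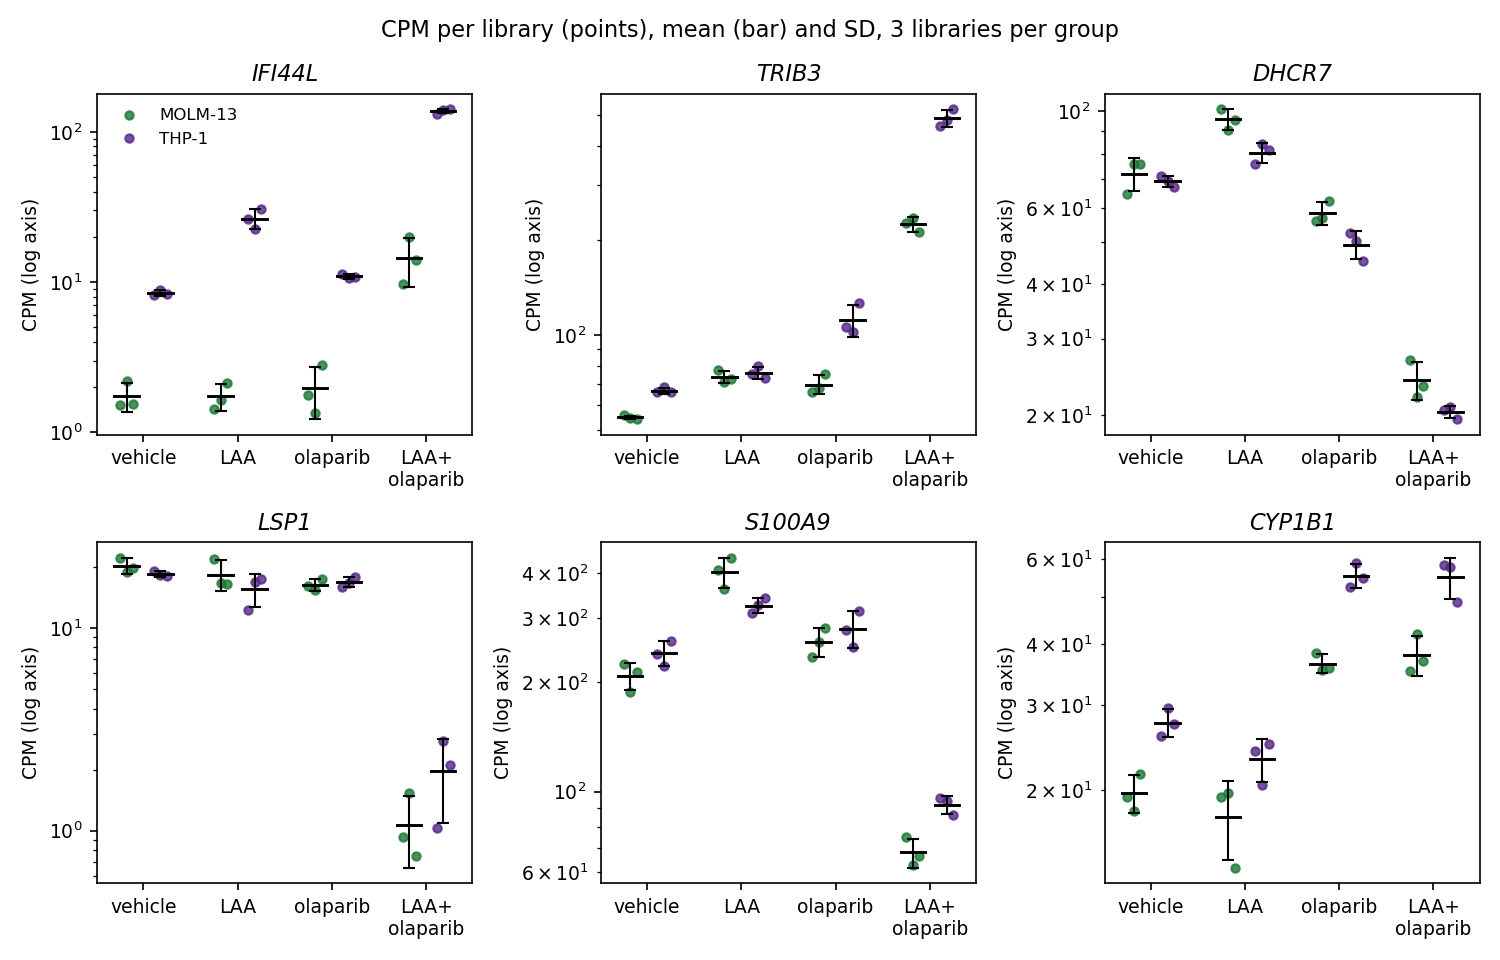
CPM on a log axis (y) of 6 genes per library (points), by treatment (x axis) and line, with the mean (bar) and SD of 3 libraries. IFI44L and TRIB3 were highest, and DHCR7, LSP1 and S100A9 lowest, in the libraries with both compounds of each line.

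**Figure D4:**
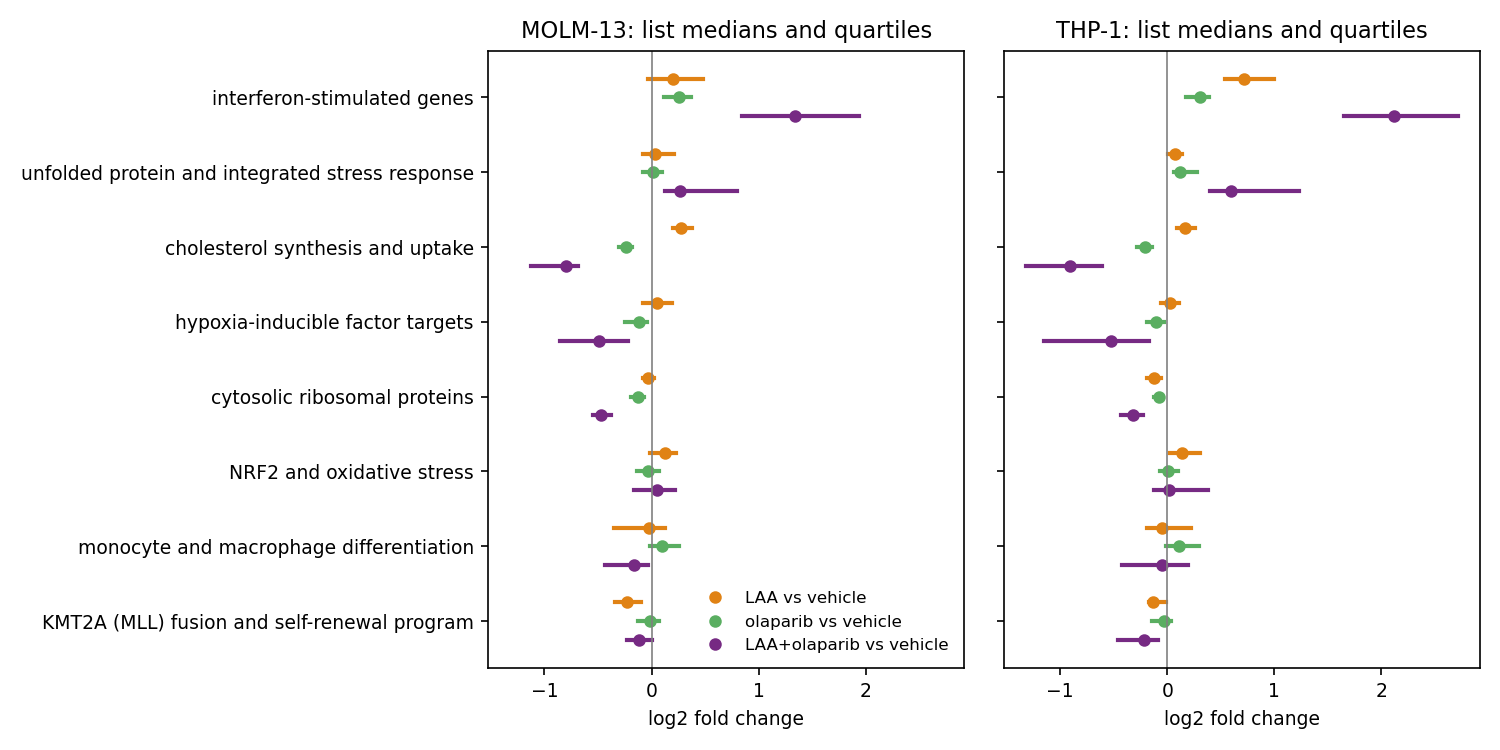
Log2 fold change against vehicle (x axis) of 8 gene lists (y axis) per line and treatment, with points for the median and lines for the quartiles of the tested members. Interferon-stimulated genes had medians of 0.71, 0.31 and 2.12 in THP-1 for LAA, olaparib and both.

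To ask whether the compounds together differed from each alone, the combination was set against the single compounds and their interaction was tested. In THP-1 KLHDC7B was 263-fold higher than with LAA and 18.9-fold higher than with olaparib, ORM1 80-fold and 18.2-fold, while SULF2 was 12.6-fold and 15-fold lower. With LAA KLHDC7B had 9 and ORM1 18 counts over the 3 libraries, so these folds are imprecise, and across the settings tried the log2 values against LAA ran from 3.09 to 8.1 for KLHDC7B and from 4.37 to 6.35 for ORM1. The interaction, the log2 change beyond the sum of both single effects, was 6.28 for KLHDC7B (edgeR adjusted p = 9.64e-09; 2.76 to 6.33 across settings), 4.08 for ORM1 (edgeR adjusted p = 3.34e-05), -3.6 for SULF2 (edgeR adjusted p = 9.7e-13) and -3 for TBC1D30. In MOLM-13 it was 2.87 for IFI44L (edgeR adjusted p = 0.000662), 2.68 for GDF15 (edgeR adjusted p = 0.000973), -3.74 for LSP1 (edgeR adjusted p = 5.26e-08) and -2.88 for S100A9 (edgeR adjusted p = 2.46e-10). KLHDC7B (4.1, edgeR adjusted p = 0.0142) lost its MOLM-13 call without vehicle replicate 2 or 3 (edgeR adjusted p = 0.159 and 0.0552). CDKN1A had a negative interaction in MOLM-13 (-0.67, edgeR adjusted p = 0.000401). In THP-1, U2AF1L5 and EIF3CL also passed, but both share reads with near-identical copies.

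Against LAA alone, 39 of 42 interferon-stimulated genes were higher and 1 lower in THP-1 (40 and 1 adjusted over the list alone; median 1.32) and 37 of 41 higher and 1 lower in MOLM-13 (37 and 1; median 1.19), at camera adjusted p of 2.38e-40 and 1.03e-29. Against olaparib alone the counts were 40 and 1 (40 and 1 adjusted over the list alone; median 1.85) and 33 and 1 (36 and 1; median 1.05), at camera adjusted p of 1.96e-46 and 1.3e-34. With an estimated correlation these adjusted p were 0.00583, 0.0256, 0.00372 and 0.0107. Cholesterol genes were lower than with LAA in 23 of 24 cases in THP-1 and 24 of 24 in MOLM-13, the same numbers as adjusted over the list alone, and hypoxia targets in 29 of 41 in each (30 and 34 adjusted over the list alone). The interaction of whole lists followed the same groups. Interferon-stimulated genes had 38 positive and 1 negative interactions of 42 in THP-1 (median 1.09, camera adjusted p = 1.32e-37) and 25 and 0 of 41 in MOLM-13 (median 1.03, camera adjusted p = 3.74e-26). Stress response genes had 24 and 1 of 35 in THP-1 (median 0.55) and 8 and 0 in MOLM-13 (median 0.33). Cholesterol genes had 0 and 21 of 24 in each line (medians -0.86 and -0.87), and hypoxia targets 2 and 18 in THP-1 and 0 and 12 in MOLM-13. Adjusted over the list alone, these 8 counts were 38 and 1, 32 and 1, 27 and 1, 18 and 0, 1 and 23, 0 and 23, 2 and 22, and 1 and 21. With an estimated correlation all 8 kept their calls, with adjusted p of 0.00726, 0.0291, 0.00185, 0.00227, 0.00185, 0.00227, 0.00259 and 0.00713 in that order. DNA replication held as well (adjusted p = 0.0074 in THP-1 and 0.0297 in MOLM-13 with an estimated correlation), and monocyte genes in MOLM-13 only (0.00584, against 0.0736 in THP-1), a difference between lines that was not tested.

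By edgeR, 1237 genes in THP-1 (659 positive, 578 negative) and 329 in MOLM-13 (115 and 214; 169 and 159 with total-count scaling) had an interaction. The THP-1 count was 810 without vehicle replicate 2 and 797 without LAA replicate 3. The MOLM-13 count was 210 without vehicle replicate 2, 218 without vehicle replicate 3, 496 without LAA replicate 2, 206 without combination replicate 2 and 210 without combination replicate 3. Against LAA, the combination called 3320 genes in THP-1 (1653 higher, 1667 lower) and 2413 in MOLM-13 (1080 and 1333; 1509 and 946 with total-count scaling). Against olaparib it called 3952 (2001 and 1951) and 1208 (467 and 741; 771 and 529 with total-count scaling). In MOLM-13 the count against LAA was 1589 without LAA replicate 1, 1388 without LAA replicate 3, 1029 without combination replicate 2 and 1392 without combination replicate 3. Against olaparib it was 624 and 632 without combination replicate 2 and 3.

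TET1, TET2, TET3, TDG, DNMT1, DNMT3A, DNMT3B, PARP1, PARP2, CDKN1A, MYC, HMOX1, ITGAM and CD14 were followed through every comparison. With LAA 2 of these 14 genes were called in THP-1, ITGAM and HMOX1 (0.53 ± 0.13, edgeR adjusted p = 0.0399). HMOX1 lost its call without each of the 6 libraries but THP-1 vehicle replicate 3 (edgeR adjusted p from 0.0634 to 0.202). CDKN1A alone was called with olaparib in THP-1. In MOLM-13 neither single compound gave a call, the smallest edgeR adjusted p being 0.0671 (ITGAM with LAA, -0.32) and 0.236 (HMOX1 with olaparib, 0.75). Set against LAA in THP-1, the combination had higher CD14 (2.2), CDKN1A (0.42) and TDG (0.29) and lower TET1 (-0.66), ITGAM (-0.56), MYC (-0.35) and DNMT3A (-0.33). Set against olaparib, CD14 (0.66), HMOX1 (0.46) and DNMT1 (0.21) were higher and ITGAM (-0.93), MYC (-0.38) and DNMT3A (-0.27) lower. In MOLM-13 TET3 (0.43) and TDG (0.41) were higher and CDKN1A (-0.46) and ITGAM (-0.44) lower than with LAA, and CDKN1A (-0.69) and ITGAM (-0.85) lower than with olaparib. Called interactions were 1.41 for CD14 (edgeR adjusted p = 0.00105) and -0.51 for ITGAM (edgeR adjusted p = 0.00926) in THP-1, and -0.53 for ITGAM (edgeR adjusted p = 0.0252) in MOLM-13 beside that of CDKN1A. Some of these calls were lost without 1 library, with edgeR adjusted p of up to 0.131 for TET1 against LAA, 0.059 for DNMT1, 0.185 for DNMT3A and 0.0681 for HMOX1 against olaparib in THP-1, and 0.19 for TET3 against LAA and 0.0937 for the ITGAM interaction in MOLM-13. Of these 14 genes only CDKN1A differed between the lines, with the combination.

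The lines were then compared for the same treatment. With the combination 1341 genes changed in the same direction in both lines and 19 in opposite directions, of 1944 and 4363 calls among 15793 genes tested in both. IFI44L, KLHDC7B, TRIB3, DHCR7, ALDOC, LSP1 and SULF2 were among the shared genes. The 569 shared higher and 772 shared lower genes compared with 107 and 162 for independent lists, and the log2 fold changes had a correlation of 0.511 across genes, which are not independent replicates. The cell content of the MOLM-13-labelled libraries was not settled, so shared calls may not be those of 2 independent systems. LAA called 59 genes in the same and 2 in opposite directions in both lines, where independent lists would share 1.22 higher and 0.923 lower. AKR1C3, IFITM1 and S100A9 were among those 59. The interactions shared 236 genes in the same and 0 in opposite directions.

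Comparisons within a line share their 3 vehicle libraries, which were not divided between the comparisons. In THP-1, LAA and the combination shared 181 calls in the same and 22 in opposite directions (112 higher and 69 lower, against 20.7 and 12.2 for independent lists), with a covariance of 0.0946 against 0.0503 and a correlation of 0.429 against 0.504 in simulated unchanged groups. Olaparib and the combination shared 42 of the 44 olaparib calls (30 and 12, against 4.06 and 1.9; covariance 0.0873 against 0.0503, correlation 0.422 against 0.504), among them CYP1B1, TRIB3 and CDKN1A, with 1 in the opposite direction. LAA and olaparib shared 11, with 1 opposite (covariance 0.0533 against 0.0505, correlation 0.431 against 0.507). In MOLM-13, LAA and the combination shared 158 calls in the same and 19 in opposite directions (42 and 116, against 6.21 and 12.9; covariance 0.0828 against 0.0463, correlation 0.43 against 0.49), and S100A9 was among the opposite ones. Simulated unchanged groups shared at most 1 call over 20 sets. No effect was simulated in them, so few calls could be shared. How many calls the shared controls add beside real effects was not measured. Part of each excess may come from the shared controls.

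The last question was which genes the lines answered differently. LAA raised interferon-stimulated genes more in THP-1 than in MOLM-13, by a median log2 difference of 0.55 (4 of 42 genes called, 28 adjusted over the list alone; camera adjusted p = 7.26e-29, adjusted p = 0.0264 with an estimated correlation). With the combination the difference was 0.59 (17 higher and 0 lower of 42; 29 and 0 adjusted over the list alone; camera adjusted p = 1.29e-21, adjusted p = 0.0271 with an estimated correlation). Stress response genes also rose more in THP-1, with 13 higher and 0 lower of 36 (20 and 0 adjusted over the list alone; median 0.3, camera adjusted p = 4.78e-16, adjusted p = 0.000416 with an estimated correlation). CDKN1A rose with the combination in THP-1 and fell in MOLM-13, a log2 difference of 1.02 ± 0.09 (edgeR adjusted p = 6.48e-09). DYSF (6.48), MFNG (4.04) and CST7 (3.28) had the largest positive differences for the combination among the named genes. DYSF had 6 counts over the 3 THP-1 vehicle libraries, and its value ran from 0.93 to 6.57 across the settings tried. Vehicle levels in MOLM-13 and THP-1 were 6.89 ± 0.602 and 0.0998 ± 0.138 CPM for DYSF, 8.82 ± 1.86 and 7.3 ± 0.93 for MFNG, and 6.29 ± 1.28 and 1.64 ± 0.516 for CST7. With olaparib MT-ATP6, a mitochondrial ATP synthase gene, differed by -0.76 ± 0.12 (edgeR adjusted p = 0.0136), at 3770 and 5510 CPM in MOLM-13 vehicle and olaparib libraries and 4280 and 3690 CPM in THP-1. That call was lost without MOLM-13 vehicle replicate 1, THP-1 vehicle replicate 1 or 2, or THP-1 olaparib replicate 2 or 3 (0 genes each). The count was 6 and 8 without MOLM-13 olaparib replicate 1 and 2. DNMT3A did not differ at the threshold for the combination (-0.5, edgeR adjusted p = 0.0522).

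The edgeR test of the line difference called 24 genes for LAA (22 higher and 2 lower in THP-1), 1 for olaparib and 364 for the combination (262 and 102) of 17089. Leaving out genes that differed between the olaparib-treated lines kept 7 for LAA and 254 for the combination. DYSF is among the genes left out, so its difference carries the same limit as the lower levels of FLT3, MEIS1 and EPB41L3. CST7 showed a like pattern, so the limit may hold for it too. It stood at 6.29 CPM with vehicle, 1.92 with LAA and 1.38 with both in MOLM-13, against 1.64 in THP-1 with vehicle. MFNG did not, falling with LAA from 8.82 to 1.79 CPM, below the 7.3 of THP-1 with vehicle. For LAA the count of line differences was 13 without MOLM-13 vehicle replicate 2 and 14 without THP-1 LAA replicate 3. For the combination it was 211 without MOLM-13 vehicle replicate 1, 240 and 213 without MOLM-13 combination replicate 2 and 3, 211 and 237 without THP-1 vehicle replicate 1 and 2, and 228 without THP-1 combination replicate 3. With vehicle alone 765 of 17089 genes differed between the lines, 202 of them by 2-fold or more, and mean log2 CPM correlated at 0.99 across genes. Single replicates of a group correlated at 0.995 to 0.9979, on log2 CPM over all genes in place of group means over tested genes. Genes at least 2-fold higher in MOLM-13 numbered 96 with vehicle, 22 with LAA, 90 with olaparib and 86 with both. Those at least 2-fold lower numbered 106, 117, 125 and 273. Because of the joint fall of genes nearly silent in THP-1, the cell content of the MOLM-13-labelled libraries is not settled. Results named MOLM-13 are those of the libraries with that label. NCAM1 stood at 10.8 CPM in MOLM-13 and 56.2 in THP-1, and TMEM176B at 0.17 and 4.13.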

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

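All splits of the libraries, the tests of the genes nearly silent in THP-1, the test of THP-1 cells in MOLM-13 libraries, the test of ribosomal genes against lists matched on level alone, and the mixed-sample and scaling tests of the interferon-stimulated genes were chosen only after the results were seen. The GC content and gene length tests and the test of other abundant genes were planned before.

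The effects of the same treatment differed between the lines in edgeR's test for 24 genes with LAA, 1 with olaparib and 364 with the combination. With LAA the named genes were DYSF, a membrane repair gene (3.86, THP-1 minus MOLM-13 on the log2 scale), the glycosyltransferase gene MFNG (2.65), the protease inhibitor gene CST7 (2.62), the transcription factor gene JUN (-0.68) and MARCKS (-0.47). MARCKS lost its call without each of the 12 libraries of the comparison (edgeR adjusted p from 0.0577 to 0.21). JUN lost it without each library but MOLM-13 LAA replicate 3 and THP-1 LAA replicate 2 (0.0528 to 0.184). DYSF lost it without each but MOLM-13 LAA replicate 2, THP-1 LAA replicates 2 and 3 and THP-1 vehicle replicate 3 (0.0528 to 0.584). With olaparib MT-ATP6 differed (-0.76), a call lost without MOLM-13 vehicle replicate 1 (edgeR adjusted p = 0.0811), THP-1 vehicle replicate 1 (0.0799) or 2 (0.0763), or THP-1 olaparib replicate 2 (0.078) or 3 (0.0533). With the combination DYSF (6.48), MFNG (4.04), CST7 (3.28) and CDKN1A (1.02) were higher in THP-1 and ROS1 (-2.05), LRRC17 (-1.62) and the ephrin receptor gene EPHB1 (-1.46) lower. LRRC17 was lost without MOLM-13 combination replicate 1 or THP-1 combination replicate 1 (edgeR adjusted p = 0.0514 and 0.0603).

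Whole lists differed between the lines too, in medians of the log2 difference. Interferon-stimulated genes differed by 0.549 with LAA and 0.595 with the combination. With olaparib the stress response list differed by 0.082 and the mitochondrially encoded genes, listed beforehand as a sign of RNA quality, by -0.712. With the combination the monocyte list differed by 0.175, the stress response list by 0.299 and the NF-kB list by 0.183. All 7 held with an estimated correlation.

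For these line differences the regroupings of labels do not decide whether chance gave the calls. Of 100 regroupings of the treatment labels, 10, 7 and 15 gave as many calls for LAA, olaparib and the combination, with up to 123, 5 and 2471 calls. With the line labels exchanged 12, 13 and 6 of 100 did, with up to 462, 343 and 1116. The highest counts with LAA (123 and 462) came from regroupings that moved all 6 labels of 1 line or 1 treatment, which put effects of treatment or line into the tested difference.

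The first pattern weighed was the joint fall of genes nearly silent in THP-1 in the MOLM-13-labelled LAA libraries. Across the 14 tested genes the common log2 fold change was -2.58 ± 0.14, and the genes' own values spread around it with a chi-square per degree of freedom of 0.71. Mean total counts of the LAA libraries were 0.915 of those with vehicle, which argues against depth. A candidate explanation is that the MOLM-13-labelled libraries may hold a second cell population whose share fell, but genes higher in MOLM-13 closed a median share of only 0.354 of the gap to THP-1 (quartiles -0.257 to 0.773), below the 0.4 set for it. A later restriction to the 69 genes at least 2-fold apart gave 0.758 (quartiles 0.463 to 0.893), which would meet that bound. The nearly silent genes closed a median share of 0.828. The cells that gained share could be THP-1 cells, a hypothesis that was tested on genes at least 2-fold lower in MOLM-13. They closed a median share of 0.113 of the gap with LAA (quartiles -0.0222 to 0.36), with 110 of the 120 genes below 0.798, the lower quartile of the nearly silent genes. A rising share of THP-1 cells would close the same part of every gap. That holds only if those cells matched the THP-1 vehicle libraries and LAA itself moved none of these genes. On those conditions the values argue against such cells as the whole cause with LAA, by a bound set after the share was seen. With the combination the share was 0.308 (quartiles -0.0594 to 1.09), which does not meet that bound. THP-1 cells unlike those libraries, and cells of another kind, stay open. A second population and genes regulated by LAA, each by its own factor, cannot be told apart by these tests. The share of the gap over 314 genes lay between the bounds set, while the later 2-fold set met the bound for a second population. Genes regulated together can also share a factor. On pooled counts the chi-square per degree of freedom was 1.55 with LAA, 3.64 with olaparib and 5.66 with the combination, at simulated p of 0.757, 0.562 and 9e-04 over 10000 sets with 1 common factor and edgeR's spread between libraries. A change of share alone therefore does not account for the combination's values.

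The second pattern was the rise of interferon-stimulated genes with the combination. In MOLM-13 the list rose by a median of 1.19 against LAA alone. The nearly silent genes stood at 5.34 CPM with LAA and 4.08 with both. That argues against a population whose share fell with LAA as the whole cause. Those genes did not follow 1 common factor with the combination, so they measure a share only roughly. THP-1 cells and cells of another kind stayed open above, so a change of cell content was not excluded in MOLM-13. With total-count scaling the smaller of the lines' medians was 1.393, and after removing the trend with GC content and length it was 1.324. These values argue against library scaling and the trend with GC content and length as the cause. An effect of the compounds on these genes is a hypothesis found and tested on the same data.

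The third pattern was the fall of ribosomal protein genes with the combination. The smaller median after removing the trend with GC content and length was -0.354, and the uncorrected THP-1 median of -0.324 lay below the lowest of 10000 random lists of like level, GC content and length (-0.29), which argues against that trend as the whole cause. Other genes in the same level range fell by a median of -0.142 in MOLM-13 and -0.132 in THP-1, between the bounds set beforehand. The ribosomal median lay below that of those genes by -0.327 in MOLM-13 and -0.193 in THP-1. Of 10000 lists of other genes matched on level alone, 0 were as low in MOLM-13 (lowest -0.447), which argues against a general fall of abundant genes as the whole cause there. In THP-1 1 was as low (lowest -0.33), short of the bound set, so there it cannot be told apart from a change of the ribosomal genes by that bound. The lists drew on only 162 different genes in MOLM-13 and 182 in THP-1. They took genes as independent, so their counts are not p-values. Camera with an estimated correlation did not call the ribosomal list (adjusted p = 0.189 in MOLM-13 and 0.537 in THP-1). Part of the fall in each line may be shared with other abundant genes.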

How the results depend on the processing

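The tests that left out genes differing between the lines were chosen only after the result was seen. Depth limits genes of few counts: KLHDC7B, ORM1 and GDF15, and DYSF in THP-1, stood under 2 CPM with vehicle, so their folds are imprecise. No called value changed sign. Counts under DESeq2-type size factors and under the stricter filter stayed within 1.5 times, and median shifts of all genes were under 0.1. Named genes had 306 calls, with a gene counted once per comparison. Of these calls 303 stayed with DESeq2-type size factors, 294 with total-count scaling, 247 on log2 FPKM with pseudocount 0.1, and 226 in every fit leaving out a library. The cause was not tested.

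With DESeq2 the counts were 577 (MOLM-13 LAA), 33 (MOLM-13 olaparib), 550 (MOLM-13 interaction), 387 (THP-1 LAA), 94 (THP-1 olaparib), and 45, 3 and 656 (line differences for LAA, olaparib and both). Without a count filter they were 502, 194, 555, 383, 124, 102, 34 and 603 in that order. On log2 FPKM with pseudocount 1 they were 134 (THP-1 LAA), 6 (THP-1 olaparib), 45 and 0 (line differences for LAA and olaparib), and with pseudocount 0.1 195 (MOLM-13 LAA), 132, 10 and 0 (line difference for olaparib). Counts of 0 there compare with 747 genes at an unadjusted p under 0.05 by edgeR, where 854 are expected by chance. With the compared groups alone they were 199 (MOLM-13 LAA), 380 (THP-1 LAA), 0 and 731 (line differences for olaparib and both). Total-count scaling gave 0 for MOLM-13 olaparib, where edgeR had 1354 genes at an unadjusted p under 0.05 and DESeq2 called 33. Without genes differing between the lines, 7 line differences for LAA stayed. An estimated correlation kept 20 of 49 list calls, fry kept 37 and called 9 of 74 others, and 191 of 1341 shared genes passed a log2 change of 1 in both lines.

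Leaving out 1 library gave, from lowest to highest in MOLM-13, 113 to 469 (LAA), 0 to 7 (olaparib), 1043 to 1578 (both), 1029 to 3168 (both against LAA), 624 to 918 (both against olaparib) and 206 to 496 (interaction). In THP-1 it gave 114 to 209, 15 to 79, 3476 to 4114, 2419 to 3116, 3079 to 3747 and 797 to 1478. For line differences it gave 13 to 22, 0 to 8 and 211 to 353, and for lists 47 to 51.

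Libraries shared only a number: correlations of same-numbered libraries ran from -0.086 to 0.116 in MOLM-13 and -0.077 to 0.038 in THP-1. With the replicate block MOLM-13 olaparib gave 4 calls, MOLM-13 LAA 308, both 2015, and in THP-1 205, 32 and 4249. The block kept 292 of 306 named calls.

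For 3 against 3 libraries 10 splits are too few for a share under 0.05. The real split alone (1 of 10) gave its count, with 0 in the others, for LAA (303), both (1972), both against LAA (2413) and both against olaparib (1208) in MOLM-13, and for LAA (243), both (4423) and both against LAA (3320) in THP-1. The highest other was 1 for THP-1 both against olaparib (3952) and 18 for THP-1 olaparib (44). For MOLM-13 olaparib (1), 2 of 10 splits gave as many, with 1 the highest other. For the interactions 2 of 100 regroupings gave as many as 329 and 1237, with highest others of 413 and 1547. These regroupings also move single effects into the interaction, so they do not settle chance.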

Other observations

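The tests in this part were chosen only after the results were seen. In THP-1 the combination raised genes of antigen presentation. Of 20 genes of MHC class I and peptide loading 17 rose and 0 fell (median 0.4, camera adjusted p = 5.89e-11, adjusted p = 0.0236 with an estimated correlation), among them the peptide transporter TAP1 (log2 fold change 1.03), PSMB9 (0.92) and B2M (0.66). MHC class II had 4 higher and 1 lower of 12 (camera adjusted p = 0.0478, adjusted p = 0.265 with an estimated correlation), with HLA-DRA at 1.51. Some HLA genes are near-identical copies, so the values of those genes are uncertain. Nucleic acid sensors had 10 higher and 2 lower of 19 (median 0.37, camera adjusted p = 5.11e-05, adjusted p = 0.00763 with an estimated correlation): the RNA sensors DDX58 (2.17) and IFIH1 (1.75) rose while TMEM173, the adaptor of DNA sensing, fell (-0.73). In MOLM-13 class I had 3 higher and 2 lower of 20 (camera adjusted p = 0.343), class II 2 and 1 of 13 (0.362), and the sensors 6 and 1 of 17 (median -0.07 while the test pointed up, 0.343), with IFIH1 at 1.31 and TMEM173 at -0.57. The difference between the lines was not tested for these lists. DDX58 and IFIH1 are also on the interferon-stimulated list. With LAA alone in THP-1, 6 sensors rose (camera adjusted p = 1.85e-05, adjusted p = 0.00715 with an estimated correlation), and 2 class II genes did (2.39e-05, and 0.0825 with an estimated correlation).

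Translation genes split in both lines with the combination. Aminoacyl-tRNA synthetases, which load amino acids onto transfer RNAs, had 16 higher and 2 lower of 18 in THP-1 (median 0.42, camera adjusted p = 4.91e-10, adjusted p = 0.00763 with an estimated correlation), led by WARS (1.96 ± 0.07) and GARS (0.94). In MOLM-13 10 rose and 2 fell (camera adjusted p = 4.21e-06, adjusted p = 0.186 with an estimated correlation), with WARS at 1.06. Translation factors with 5' TOP messenger RNAs went the other way, with 0 higher and 12 lower of 16 in THP-1 (camera adjusted p = 2.06e-06, adjusted p = 0.0425 with an estimated correlation) and 0 and 11 in MOLM-13 (camera adjusted p = 3.25e-07, adjusted p = 0.186 with an estimated correlation), EEF1A1 at -0.55 and -0.51. Proteasome genes had 11 higher and 0 lower of 26 in THP-1 (camera adjusted p = 5.11e-05, adjusted p = 0.118 with an estimated correlation) and 1 and 0 in MOLM-13 (0.353). Oxidative phosphorylation genes had 3 and 6 of 29 in THP-1 (0.267) and 0 and 6 in MOLM-13 (camera adjusted p = 0.000287, adjusted p = 0.475 with an estimated correlation). Replication-dependent histones had 0 and 3 of 11 in THP-1 (camera adjusted p = 0.0228, adjusted p = 0.0962 with an estimated correlation) and 0 and 2 in MOLM-13 (0.128).

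Among 9 protein-coding genes nearly silent in MOLM-13 and seen in THP-1 olaparib libraries, the highest mean was 0.473 CPM in THP-1 vehicle libraries, against 6.61 for the genes nearly silent in THP-1. With the combination the common log2 fold change of the 14 tested genes was -2.96 ± 0.14 and with olaparib -0.74 ± 0.12. The genes' own values ran from -7.75 to -1.53 with the combination. Their chi-square per degree of freedom was 3.31 (chi-square p = 4.36e-05), so 1 common value does not describe them. With olaparib it was 0.798. Some genes went against identical cultures: NCAM1 stood at 10.1 CPM in MOLM-13 and 56.1 in THP-1 with LAA.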
